A study of Escherichia coli ATCC 8739 with 3 samples.

How the data were processed

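RNA sequencing libraries from 3 engineered strains of Escherichia coli ATCC 8739 were compared, with 1 library for each of the strains CAR005, IspG1 and G4H14. Per the labels' protocols, cells were grown in LB medium in shaken flasks, total RNA was extracted with Trizol, phenol and chloroform, and the RNA was cleaned on a column with a DNase I treatment before Illumina library preparation. Samples were grouped by the strain label alone. No label gives a replicate, a batch or a sequencing date.

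Reads were aligned with Bowtie2 version 2.2.5, per the submitters' processing notes. The counting program, its strand setting, its treatment of reads with several matches and the genome build are not given in the sources used here. Per the file headers, the authors deposited for each of 4200 ATCC 8739 locus tags the coding length in base pairs, a raw read count and an RPKM value (reads scaled by coding length and library total). Recomputing RPKM from the deposited count, the coding length and the summed count of the same library gave the deposited RPKM for every tag with reads, with a largest relative deviation of 1.1e-09. The authors' RPKM is therefore scaled to the reads counted in these tags and carries no information beyond the counts. Coding lengths were multiples of 3 for 99.5% of tags, so they hold no untranslated regions.

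The deposited files give locus tags without gene names. The gene table used here is of strain K-12 MG1655, and 0 of the 4200 tags matched any identifier in it. No gene names or coordinates were therefore assigned. The planned values for ispG and ispH, the 49 gene lists fixed before the data were examined (isoprenoid, iron-sulfur, nucleotide, ribosome, stress and other pathways) and the rule for named genes could not be applied to unnamed tags. In their place the text prints 4 tags, the 2 with the highest and the 2 with the lowest log2 ratio between IspG1 and CAR005 among tags that passed the read minimum. It describes the others by abundance class and by runs of consecutive tag numbers, groupings that were chosen after seeing the data.

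Counts were expressed as CPM (read counts scaled to a common library total) with TMM factors from edgeR 4.0.16 in R 4.3.3, calculated over the 3 libraries. The factors were 0.856 for CAR005, 0.742 for IspG1 and 1.57 for G4H14. A log2 ratio was log2 of (CPM + 1) in one library over (CPM + 1) in the other, which understates differences of low tags. A tag entered a comparison with at least 50 reads in 1 of its libraries, and was counted as higher or lower at a ratio of at least 2-fold. With 1 library per strain there is no replicate check, no test between strains was possible and no p-value is given. Every comparison is one of libraries, not of strains as populations. Intervals on ratios of single tags are exact (Clopper-Pearson) 95% intervals on the 2 counts. They cover counting error only. A count of 0 allows up to 3 reads, which is 0.652 CPM in CAR005, 0.646 CPM in IspG1 and 0.602 CPM in G4H14 before TMM scaling.

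The alternatives fixed before the data were examined were median-centred ratios, CPM by total count without TMM factors, pseudocounts of 0.1 and 5, no read minimum, a minimum of 200 reads, and the authors' RPKM. After seeing the data, a per-kilobase background was subtracted from the G4H14 counts in 2 ways, each followed by CPM on the new total and the same 50-read minimum. The first used the median G4H14 RPKM of the 690 tags under 10 RPKM in both other libraries. The second, called the local background, used the median G4H14 RPKM of tags whose mean over CAR005 and IspG1 was from 5 to 20 RPKM, within each of 10 equal parts of the summed coding length in tag order. Only tags of at least 300 bp with reads in G4H14 were used, 796 in all. These tags carry some expression of their own, so this level can be too high. Tags under the assumed level were set to 0, and the counts were also taken without them. Other additions were a restriction to tags at 500 RPKM or more in at least 1 compared library, with total-count CPM, and TMM factors over CAR005 and IspG1 only. Locus tags are by convention numbered along the chromosome, and 98.2% of successive tags in the files had consecutive numbers.

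The ratio and background calculations were tested on simulated data over the 4200 tags, with Poisson counts drawn from the CAR005 levels. Simulated ratios used total counts, with median-centring for the recovered shares, so TMM scaling was not tested. For IspG1 against CAR005 the calculations recovered 100% of 200 changed tags at 3-fold and 45.5% at a true change of exactly 2-fold, the threshold itself. For G4H14 against CAR005 the recovered shares were 100% and 54.0%, and for G4H14 against IspG1 they were 99.5% and 43.5%. All changed tags were well covered in CAR005, and these simulated libraries held no background. The shares therefore do not cover low tags or the real G4H14 library. A background of known size added to the simulated G4H14 library was estimated at 105% of its true level. A background that followed position, estimated as the local background, came out at 111% of its true level at the median of the 10 parts (108% to 116%). With no other difference from CAR005, subtraction then left 251 lower and 127 higher tags of 3393 with the single level (93 of the lower set to 0), and 413 lower and 0 higher of 3279 with the local background (145 set to 0). Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.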

Results

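The transcriptomes of 3 engineered strains of E. coli ATCC 8739 were compared in the context of balancing IspG and IspH. These are iron-sulfur enzymes that act in succession at the end of the methylerythritol phosphate pathway, the bacterial route to isoprenoid precursors. The labels name the strains CAR005, IspG1 and G4H14 and give no genotype. Each strain was represented by 1 library, so every value below is that of a single library. The 4200 locus tags received 4602490 reads in CAR005, 4643241 in IspG1 and 4982281 in G4H14.

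The distribution of levels over tags was similar in CAR005 and IspG1 and different in G4H14. It does not show which libraries were most alike tag by tag. The median RPKM of a tag was 68.0 in CAR005, 51.1 in IspG1 and 142 in G4H14. The lower quartile was 15.6 RPKM in CAR005 and 14.3 in IspG1, against 99.1 in G4H14. At least 50 reads were counted for 3276 tags in CAR005, 3246 in IspG1 and 4084 in G4H14. The number of tags with 0 reads was 40 in CAR005, 40 in IspG1 and 13 in G4H14. The 50 most abundant tags of each library held 27.6% of the reads in CAR005, 33.9% in IspG1 and 18.2% in G4H14. Across tags, which are not independent replicates, the rank correlation of read count with coding length was 0.29 in CAR005, 0.29 in IspG1 and 0.61 in G4H14.

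**Figure D1:**
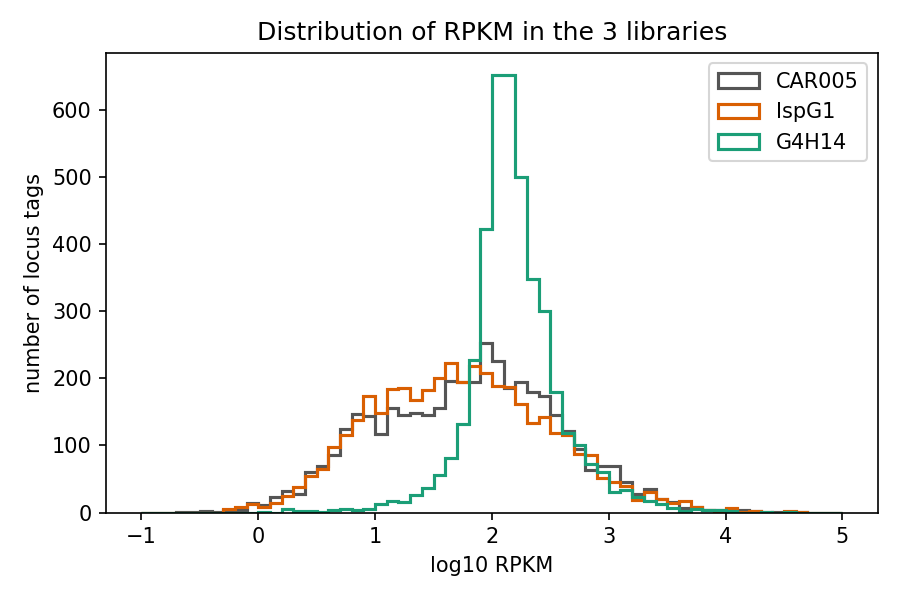
Histogram of log10 RPKM (x axis) over locus tags with at least 1 read (y axis, number of tags) in the libraries of CAR005, IspG1 and G4H14, 1 library per strain. The lower quartile of G4H14 lies at 99.1 RPKM, against 15.6 in CAR005 and 14.3 in IspG1.

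IspG1 was compared with CAR005 to describe the library of the strain named for IspG against that of CAR005. Of 3366 tags compared, 299 were at least 2-fold higher in IspG1 and 338 were at least 2-fold lower, and 2729 (81.1%) lay within 2-fold. The interquartile range of the log2 ratio ran from -0.55 to 0.45. By total count, without TMM factors, 210 tags were higher and 516 lower, and with median-centred ratios 338 were higher and 286 lower. The higher share of these calls was 46.9% with TMM, 28.9% by total count and 54.2% when median-centred, so which direction held more calls depended on the scaling. TMM moved the median log2 ratio of all compared tags from -0.27 to -0.07.

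The highest ratios belonged to EcolC_3993 and EcolC_3995. EcolC_3993, of 1341 bp coding length, had 270 reads in CAR005 and 9857 in IspG1, or 68.5 and 2859 CPM with TMM factors. Its log2 ratio was 5.36 (95% interval of the counts 5.21 to 5.56). EcolC_3995, of 1191 bp, had 602 and 17288 reads and a log2 ratio of 5.03 (4.92 to 5.16). The lowest ratios belonged to EcolC_2321 and EcolC_0950. EcolC_2321, of 669 bp, had 7197 reads in CAR005 and 161 in IspG1, or 1827 and 46.7 CPM, and a log2 ratio of -5.26 (-5.52 to -5.06). EcolC_0950, of 735 bp, had 3859 and 192 reads and a log2 ratio of -4.11 (-4.35 to -3.93).

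**Figure D2:**
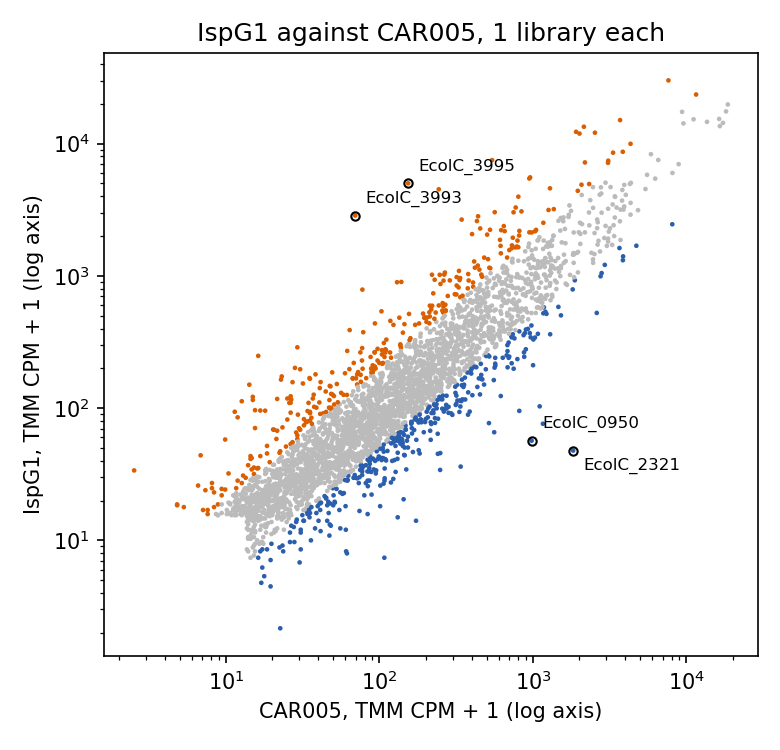
TMM-scaled CPM plus 1 in CAR005 (x axis, log scale) and IspG1 (y axis, log scale), 1 point per locus tag with at least 50 reads in either library. Orange points are at least 2-fold higher in IspG1 (299 tags), blue points at least 2-fold lower (338 tags), grey points within 2-fold, and open circles mark EcolC_3993, EcolC_3995, EcolC_2321 and EcolC_0950.

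Part of the tags that differed between IspG1 and CAR005 stood in runs in the tag order, more than after shuffling. Of the 299 higher tags, 126 (42.1%) stood in 24 runs of at least 3 consecutive tag numbers, and of the 338 lower tags 91 (26.9%) stood in 23 such runs. When the calls were shuffled over the compared tags 1000 times, runs of this length held at most 22 higher and 32 lower tags. The shuffle treats tags as independent, which genes of the same operon (transcribed together) are not. An excess over it is therefore not by itself particular to these strains. Over 2939 pairs of neighbouring tags the log2 ratios had a Pearson correlation of 0.53 and a Spearman correlation of 0.48, values across genes that are not independent replicates. The longest higher run held 15 tags, with 2367 reads in CAR005 and 10766 in IspG1, and a median log2 ratio of 2.91. A run of 6 tags carried the most reads among the 6 longest higher runs, with 33227 reads in CAR005 and 113051 in IspG1 and log2 ratios from 1.61 to 2.24. The longest lower run held 9 tags, with 15928 reads in CAR005 and 3540 in IspG1 and a median log2 ratio of -1.83.

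The differences between IspG1 and CAR005 were found in all abundance classes from 5 RPKM upward. Among the 232 tags with a mean of at least 1000 RPKM over these libraries, 45 were higher and 23 lower in IspG1 with TMM factors, against 33 and 30 by total count. Among the 1174 tags from 100 to 500 RPKM, 116 were higher and 124 lower with TMM factors, and 77 and 192 by total count. Among the 1301 compared tags from 20 to 100 RPKM these numbers were 92 and 154, and 70 and 230 by total count. Among the 414 from 5 to 20 RPKM they were 14 and 12, and 7 and 20 by total count. Of the 564 tags at 500 RPKM or more in either library, 75 were higher and 96 lower by total count, so the direction at abundant tags also depended on the scaling. The 232 most abundant tags together held 46.7% of the reads in CAR005 and 53.4% in IspG1.

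G4H14 was compared with the same CAR005 library. Low tags were higher in G4H14. Most abundant tags were at least 2-fold lower with TMM factors, but by total count most lay within 2-fold of CAR005. Of 4085 tags compared, 1315 were at least 2-fold higher and 742 at least 2-fold lower with TMM factors. By total count these numbers were 1997 and 66, which moved the higher share of calls from 63.9% to 96.8% and the median log2 ratio of all compared tags from 0.09 to 0.95. Of the 829 compared tags with a mean of 5 to 20 RPKM over CAR005 and IspG1, 766 were higher in G4H14 and 0 lower. Of the 232 tags at 1000 RPKM or more, 2 were higher and 216 lower with TMM factors, and 5 and 48 by total count. Their median log2 ratio was -1.53 with TMM factors and -0.66 by total count.

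The level of tags that had few reads in the other libraries was raised nearly throughout G4H14. The 690 tags under 10 RPKM in both CAR005 and IspG1 had a median of 4.83 RPKM in CAR005, 4.88 in IspG1 and 70.4 in G4H14, and 98.6% of them were at least 2-fold higher in G4H14 than in both others. Within these tags the count in G4H14 had a rank correlation of 0.86 with coding length. Position was examined for the 796 tags with a mean of 5 to 20 RPKM in the other libraries, at least 300 bp and reads in G4H14. Their G4H14 median was 108 RPKM in the first of 10 equal parts of the summed coding length, 74.3 in the fifth and 110 in the last. The medians of the same tags in CAR005 were 9.42, 10.6 and 9.03 RPKM, and in IspG1 they were 10.4, 8.21 and 10.5 RPKM, also lowest in the fifth part.

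**Figure D3:**
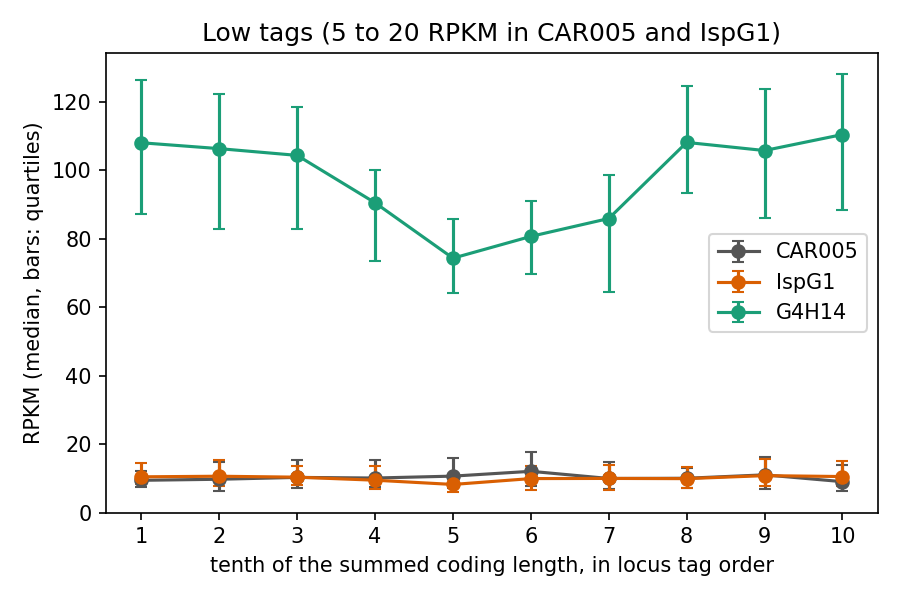
RPKM (y axis, median with quartiles as bars) of locus tags with a mean of 5 to 20 RPKM over CAR005 and IspG1, in 10 equal parts of the summed coding length in tag order (x axis), for each library. Only tags of at least 300 bp with reads in G4H14 are included. G4H14 lies between 74.3 and 110 RPKM, lowest in the fifth part, and the medians of CAR005 and IspG1 lie between 8.21 and 12.05 RPKM.

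Subtracting this level from G4H14 changed the comparison with CAR005. If the level is RNA of the strain, which stays open, the subtraction removes expression. After subtraction of 70.4 RPKM from every tag, 962 tags were higher and 219 lower among 3630. Over the whole coding length this level would amount to 28.8% of the G4H14 reads. With the local background, which would amount to 39.9% of the reads, 373 were higher and 577 lower among 3399. Fewer reads than these shares were removed, since no count was taken under 0. Either subtraction sets tags under the assumed level to 0, and so makes lower calls of its own. Of the 219 lower tags 83 had been set to 0, and of the 577 lower tags 282 had been, while 486 of the 577 were higher in G4H14 by total count. Without tags set to 0, 962 were higher and 136 lower, and with the local background 373 were higher and 295 lower. In simulated libraries with a background and no other difference, the single level gave 127 higher and 251 lower tags and the local background 0 and 413, so the lower calls after subtraction are not counted here as lower expression in G4H14. Of the 495 tags at 500 RPKM or more in either library, 8 were higher and 61 lower by total count, and 426 (86.1%) lay within 2-fold of CAR005. Over the 576 tags at 500 RPKM or more in any library, the median log2 ratio of G4H14 over CAR005 was -0.48 by total count, -0.21 after background subtraction and -0.09 with the local background. Of these 576, 501 (87.0%), 531 (92.2%) and 533 (92.5%) lay within 2-fold of CAR005 on the respective scales.

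G4H14 was compared with IspG1 to set the libraries other than CAR005 side by side. Of 4086 tags, 1449 were at least 2-fold higher in G4H14 and 731 lower with TMM factors. By total count 2468 were higher and 219 lower, so the higher share of calls was 91.8% against 66.5%, and with median-centred ratios it was 53.0%. The median log2 ratio of all compared tags was 0.36 with TMM factors and 1.43 by total count. After background subtraction 1564 were higher and 375 lower among 3622, and with the local background 934 were higher and 734 lower among 3395, so the higher share was 80.7% or 56.0%. Of these lower tags 77 and 288 had been set to 0, and without them the higher share was 84.0% or 67.7%. Of the 530 tags at 500 RPKM or more in either library, 43 were higher and 167 lower by total count, and 320 (60.4%) lay within 2-fold.

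The tags with the extreme ratios between IspG1 and CAR005 lay nearer to CAR005 than to IspG1 in G4H14. EcolC_3993 had 834 reads and EcolC_3995 had 1033 reads in G4H14. Their log2 ratios of G4H14 over IspG1 were -4.74 (95% interval of the counts -4.85 to -4.65) and -5.24 (-5.34 to -5.16). Over CAR005 they were 0.63 (0.43 to 0.84) and -0.21 (-0.36 to -0.07). The G4H14 level of EcolC_3993, 125 RPKM, lay close to the local background of 110 RPKM, and that of EcolC_3995 was 174 RPKM. The ratios over CAR005 were 0.78 and 0.39 after background subtraction, and -0.89 and -0.10 with the local background, so their direction is not settled. Those over IspG1 were -4.38 and -4.43, and -6.05 and -4.92 with the local background. By total count the ratios over CAR005 were 1.497 for EcolC_3993, past 2-fold, and 0.66 for EcolC_3995, with the sign turned, and those over IspG1 were -3.66 and -4.16. EcolC_2321 had 17294 reads in G4H14, with log2 ratios of 5.53 (5.34 to 5.79) over IspG1 and 0.27 (0.23 to 0.31) over CAR005. The ratio of EcolC_2321 over CAR005 was 1.15 by total count and 1.60 after background subtraction, both past 2-fold, and over IspG1 it was 6.60 and 7.06. EcolC_0950 had 3499 reads, with log2 ratios of 2.98 (2.79 to 3.22) over IspG1 and -1.13 (-1.20 to -1.07) over CAR005, against -0.26 by total count and 0.11 after subtraction over CAR005, and 4.05 and 4.42 over IspG1.

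Across all 3 libraries, G4H14 stood apart most often when low tags were included, with TMM factors, by total count or after background subtraction. With the local background it did so only when lower calls and tags set to 0 were counted. Lower calls after subtraction are not taken here as lower expression. Which library stood apart most often at abundant tags depended on the scaling. Among tags with at least 50 reads in 1 library, 196 were at least 2-fold apart in CAR005 from both others in the same direction, 386 in IspG1 and 1625 in G4H14. Of the 386 apart in IspG1, 203 were higher and 183 lower in IspG1. By total count 98 were higher and 451 lower in IspG1, after background subtraction 129 and 431, and with the local background 159 and 399. By total count 1071 of 1338 tags from 20 to 100 RPKM were at least 2-fold higher in G4H14 than in IspG1. There a tag lower in IspG1 than in CAR005 readily stood apart from both, and a higher one did not. The direction by total count thus partly follows from the G4H14 level. Of the 1625, 1148 were higher in G4H14. With the local background 845 stood apart in G4H14, 286 higher and 559 lower, against 558 in IspG1. Of the 559, 325 had been set to 0. Without tags set to 0, 520 stood apart in G4H14, 234 of them lower, and 531 in IspG1. By total count 3 tags at 500 RPKM or more were higher and 48 lower in G4H14. Among the 576 tags at 500 RPKM or more in any library, 54 stood apart in CAR005, 107 in IspG1 and 328 in G4H14 with TMM factors, and 327 of the 328 were lower in G4H14. By total count 12 stood apart in CAR005, 115 in IspG1 and 51 in G4H14, and with ratios centred on the median of these tags 12, 140 and 18. After background subtraction these numbers were 10, 145 and 27, and with the local background 11, 154 and 23. The direction of the tags apart in IspG1 depended on the scale, with 99 higher and 8 lower with TMM factors, 69 higher and 46 lower by total count, 67 and 78 after background subtraction, and 66 and 88 with the local background. The standard deviation across these 576 tags of the log2 ratio by total count was 1.10 for IspG1 against CAR005, 0.53 for G4H14 against CAR005 and 1.20 for G4H14 against IspG1. With TMM factors it was 1.11, 0.53 and 1.20, and with the local background 1.10, 0.56 and 1.31. The median log2 ratio of G4H14 over CAR005 at these tags was -1.35 with TMM factors and -0.48 by total count. Its spread was 0.53 on both scales, so TMM factors shifted these tags together. The 327 lower tags are therefore not counted here as lower expression in G4H14.

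By total count or after background subtraction, but not with TMM factors, most abundant tags that differed between IspG1 and CAR005 lay within 2-fold of CAR005 in G4H14. With TMM factors 25 of 100 tags higher in IspG1, 12 of 63 lower in IspG1 and 88 of all 576 (15.3%) did, and the median log2 ratio of the 576 was -1.35. After background subtraction, 62 of the 75 abundant tags higher in IspG1 and 94 of the 100 lower in IspG1 were within 2-fold of CAR005, and with the local background these counts were again 62 and 94. By total count they were 58 and 93. At least 2-fold back from IspG1 were 67 of the 75 and 78 of the 100 after background subtraction, 66 and 88 with the local background, and 69 and 46 by total count. By total count most of the lower tags were thus less than 2-fold back from IspG1, with a median log2 ratio of G4H14 of 0.96 over IspG1 and -0.39 over CAR005. The shares after subtraction, 82.7% of the higher and 94.0% of the lower tags, compare with 92.2% of all 576 abundant tags. Without the restriction to abundant tags, over the 3656 tags with at least 50 reads in any library after background subtraction, 128 of 216 higher tags (59.3%) and 446 of 517 lower tags (86.3%) were within 2-fold of CAR005, and 121 of 212 and 435 of 517 with the local background (3458 tags). Of all tags compared between G4H14 and CAR005, 67.5% of 3630 after background subtraction and 72.1% of 3399 with the local background lay within 2-fold. After either subtraction, with or without the restriction, the higher tags thus lay within 2-fold less often than tags in general. The lower tags did so more often. Without the restriction, tags in general had at least 50 reads in G4H14 or CAR005, a set not matched in abundance. The higher and lower tags were chosen on the CAR005 and IspG1 libraries, so part of this pattern can come from variation of those single libraries. The 6-tag run with the most reads had 7219 CPM in CAR005, 24347 in IspG1 and 5141 in G4H14 after background subtraction. The 15-tag run had 514, 2319 and 438 CPM, its G4H14 level of 88.3 RPKM lying close to the local background of 80.6 RPKM, and the 9-tag lower run had 3461, 762 and 2661 CPM.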

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

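The scaling between libraries changed the counts of tags more than the pseudocount or the read minimum did. The background subtractions, the restriction to abundant tags and the 2-library TMM factors were chosen after seeing the data. Leaving out tags set to 0 by a subtraction was too. For IspG1 against CAR005, 516 tags were lower by total count and 516 by the authors' RPKM, and at 500 RPKM or more 75 were higher and 96 lower, from fewer tags compared. For G4H14 against CAR005 the higher and lower counts were 1997 and 66 by total count, 2004 and 66 by RPKM, and 8 and 61 at 500 RPKM or more. There 219 were lower after background subtraction (136 without tags set to 0), and with the local background 373 were higher either way and 295 lower without tags set to 0. For G4H14 against IspG1 they were 2468 and 219 by total count, 2473 and 219 by RPKM, and 43 and 167 at 500 RPKM or more. There 375 were lower after background subtraction (298 without tags set to 0), and with the local background 934 were higher either way and 446 lower without tags set to 0. Tags apart in CAR005 numbered 124 by total count, 130 with a pseudocount of 5, 93 after either subtraction (82 and, with the local background, 65 without tags set to 0) and 12 at 500 RPKM or more. Their direction depended on the scale. It was 79 higher and 117 lower in CAR005 with TMM factors, and 6 and 118 by total count. After background subtraction it was 28 and 65, and with the local background 56 and 37. Tags apart in IspG1 numbered 115 at 500 RPKM or more. Tags apart in G4H14 numbered 1044 after background subtraction, 845 with the local background (948 and 520 without tags set to 0) and 51 at 500 RPKM or more. The other 65 of these counts and background levels stayed within 1.5 times or the quartiles of the silent tags. The log2 ratio of G4H14 over CAR005 changed sign for EcolC_3995, to 0.66 by total count and 0.39 after background subtraction, for EcolC_0950, to 0.11 after subtraction and 0.26 with the local background, and for EcolC_3993, to -0.89 with the local background. The cause of these changes was not tested beyond the construction of each scale. No replicate could be left out, with 1 library per strain. The alternatives for the gene lists and for ispG and ispH were not run, since the tags have no names here.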

Other observations

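The test of the share of lower calls was planned before its result was seen, and the other tests in this part were chosen after seeing the data.

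A run of 6 neighbouring tags that was higher in IspG1 was also higher in G4H14 than in CAR005. It covered 3252 bp of coding length and had 153 CPM in CAR005, 604 in IspG1 and 858 in G4H14 after background subtraction, or 796 in G4H14 with the local background. A run of 9 tags covering 9414 bp had 129, 641 and 619 CPM, but its G4H14 level of 118 RPKM lay close to the local background of 106 RPKM, and with that background G4H14 had 211 CPM. After subtraction of 70.4 RPKM, 216 tags were at least 2-fold higher in IspG1 than in CAR005, 962 in G4H14 and 65 in both, where independent lists would share 56.8. These lists cover the 3656 tags with at least 50 reads in any of the 3 libraries, more than the 3630 of G4H14 against CAR005 alone. In the lower direction over the same tags 517, 235 and 28 were called, and independent lists would share 33.2. With the local background the shared calls were 37 higher, against 22.9 for independent lists, and 56 lower, against 93.7, over 3458 tags. Of the shared lower tags, 11 of 28 and 28 of 56 had been set to 0 by the subtraction. Both comparisons use the single CAR005 library, so part of any overlap can come from that library. The expected numbers treat all tags alike and do not allow for abundance. The differences from them are therefore not read as shared or opposed change.

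Low tags were higher in G4H14 than in both other libraries, and a difference in sequencing depth was argued against, since the silent tags had 15.5 times as many raw reads in G4H14 as in CAR005 (230775 against 14912) while the library totals differed by a factor of 1.08. Genomic DNA reads in the G4H14 library may account for the pattern, since the level of low tags varied with tag order. The fitted highest level was 1.36 times the lowest, above the 1.34 reached in 1000 shuffles of blocks of 20 tags. The fitted peak lay at the junction of the last and first tags. Whether the course was smooth was not tested: the G4H14 median was 85.8 RPKM in the seventh of the 10 parts and 108 in the eighth. The same fit gave 1.24 in IspG1, above its shuffled maximum of 1.20 and with its peak at 2.88% of the tag order, about the same place, although that library lacked the raised level, so the peak's place is not particular to G4H14. It gave 1.13 in CAR005, reached by 41 of 1000 shuffles, with the peak at 48.6% of the tag order. The low tags were chosen on the mean of CAR005 and IspG1. Opposite trends in these libraries, and so the IspG1 peak, can come from that choice. The level in G4H14 was not uniform, with a median of 47.6 RPKM for tags under 5 RPKM in both others and 82.6 for tags under 20. RNA from normally silent genes in strain G4H14 stays open, because with 1 library a general rise in 98.6% of silent tags cannot be told apart from DNA reads, and RNA could follow gene copy number along the chromosome too.

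By total count, 71.1% of the 2-fold calls between IspG1 and CAR005 were lower in IspG1. Abundant tags taking a larger share of the counts could contribute. When the 50 most abundant tags of either library (72 tags) were left out of totals and comparison, 257 tags were higher and 372 lower, and the lower share was 59.1%. This is between the 55% or less that the explanation required and the 71.1% before, so whether it accounts for the whole excess by total count cannot be told apart from a wider difference between the strains. The excess itself depended on the scaling: the lower share was 53.1% with TMM factors and 45.8% with median-centred ratios, so an excess across the strain is not shown.

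A total of 11 tags had 0 reads in every library, although the G4H14 background of 70.4 RPKM would give each of them 65.2 to 347 reads. Near-identical copies whose reads were not counted are a candidate explanation: 6 of the 11 formed 3 pairs of equal coding length, and in 10000 random draws of 11 tags at most 5 shared a length. Removal of these regions from all 3 strains was not tested and stays open. A further 8 tags had 3 or fewer reads in G4H14 where at least 50 would be given by the background.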
